A study of Oryza sativa with 8 samples.

How the data were processed

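The series holds 8 arrays of the NIAS 22K rice oligo array, each with treated and untreated Nipponbare scutellum callus in 2 dyes. Per the labels, callus was grown for 30 d with 10 µM of 2,4-D, a synthetic auxin, and then kept for 3 d with or without 50 µM of ABA or GA. ABA has arrays 24 and 20 with the treated sample in Cy3 and arrays 19 and 23 with it in Cy5; GA has arrays 04 and 05 in Cy3 and 07 and 08 in Cy5. The array numbers are those in the labels and do not overlap between hormones.

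The deposited values are log10 ratios, LOWESS-normalized by the authors per the labels; the log base is not stated and was taken as log10, which is the convention of this array's software. Counts of called probes do not depend on the base, but folds do. Values were turned into log2 with 3.32 log2 units per log10 unit. As deposited, arrays of opposite dye orientation of 1 hormone correlated at −0.60 to −0.51 for ABA and −0.82 to −0.70 for GA. The table was therefore read as 1 fixed dye ratio on all arrays, taken as Cy5 over Cy3, although the labels describe treated over untreated, and arrays with the treated sample in Cy3 were turned. A few marker genes (PM1, EM, PP2C30, GA20OX3, AMY1.2) were looked at when the direction was set, so their direction is not independent evidence of it. The background and spot quality of the arrays are not analysed here, and the software settings behind the ratios are not given in the sources used here.

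Of 22575 features, 17788 are listed with a gene in the annotation given, 17769 of them with 1 gene, for 15641 distinct genes. Gene names came from the RefSeq annotation of ASM3414082v1 (Oryza sativa Japonica Group), which named 2117 genes on 2457 probes. Exact zeros (92 to 243 per array, 1 to 6 of them on listed probes) were treated as missing, and a probe needed at least 3 values per hormone, which left 17782 probes. The 4787 unlisted features were left out because no gene could be given for them. These choices on zeros and unlisted features were made after the values were seen; the tests, the alternatives tried first and the rule for named genes were chosen before the data were examined.

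Each probe was fitted with limma 3.58.1 in R 4.3.3, with a mean for ABA, a mean for GA and a dye term shared by both, over 8 arrays with 5 residual degrees of freedom and 3.93 prior degrees of freedom. The ABA and GA means were tested against 0 and against each other, and probes were called at a Benjamini-Hochberg adjusted p under 0.05. The median SE was 0.0396 for a hormone mean and 0.0560 for their difference. No count of reads or molecules applies to these ratios. The SD of a gene over 4 arrays, printed with it, gives its spread between arrays, dye bias included. The tests instead use the residual spread left after the dye term is fitted. The fit was tested on simulated data with 17782 probes of which 200 changed. It recovered 95.5 to 98.5 percent of changes of 0.5 on the log2 scale and 100 percent of changes of 2. Of its calls 3.45 to 5.26 percent were false. The simulation had noise independent between arrays, 1 dye effect for both hormones and far fewer changed probes than were called here. Its rates therefore need not hold for the counts below.

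Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, and again with an estimated correlation, where at least 5 genes were measured, with adjustment over the lists within each comparison. Of 22 lists fixed before the data were examined, 6 had enough members, since most genes carry only a locus number. A further 37 lists matched on gene symbols, of which 35 were tested, were written after the annotation names and the arrays' overall values had been seen and before the value of any single gene was. Names shared by other proteins were taken out after the marker genes above had been looked at and before any list was tested, and a ribosomal name was put back after the list tests had run once. Membership counts use the call over all probes, and for the lists fixed first also the call adjusted over the list alone.

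Named genes were, per hormone, the 8 with the largest rise and the 8 with the largest fall among called probes with 1 named gene and the same sign on all 4 arrays, and the 5 largest in each direction of ABA minus GA with no overlap between the arrays of either hormone. From each fixed list the 2 members with the smallest adjusted p per hormone were taken. Where a gene had several probes, the one with the smallest p is named and a differing one is given. Genes named beyond this rule as members of symbol-matched lists were chosen after their values were seen.

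The alternatives tried were no dye term, a dye term for each hormone, each hormone fitted on its own arrays, median centring, scale and quantile normalization between arrays, robust moderation, array weights by the gene-by-gene method of limma, probes with a value on every array only, Spearman correlation, a 2-fold minimum, a stricter adjusted p of 0.01, means over the probes of a gene, an estimated correlation for lists, and leaving out each array in turn. Keeping unlisted features, keeping exact zeros, turning the GA arrays for the comparison of the hormones, fitting all 4 amylase genes without the dye term, and symbol lists with no names taken out were added after the data were seen. A change of sign where neither setting passed the test was counted as no change. Agreement of the hormones was set beside 100 simulated draws with no change and the untreated sample shared or separate, with a residual spread assumed from the fit. A shared untreated sample was given the residual SD of each probe, and this choice fixes the simulated r. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.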

Results

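Scutellum callus of the rice variety Nipponbare was treated with abscisic acid (ABA, a hormone of stress and seed maturation) or gibberellin (GA, a hormone of growth and germination) and compared with untreated callus on 4 arrays per hormone. The labels attach dormancy to ABA and germination to GA, and the comparisons below ask which genes each hormone changed and whether the hormones changed the same genes. Values are log2 of treated over untreated, ± SD over n = 4 arrays unless another error is named. The SD includes the dye bias of each probe, since each hormone has 2 arrays in either dye orientation. The direction of every value rests on the dyes in the labels and on the usual convention of this array's software, as set out under the processing. It is likely but not certain for ABA; for GA too few genes known to respond were measured to check it, so every rise or fall under GA is as labelled and stays open.

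Under ABA, the largest named rise was that of PM1 (PM19L), a plasma membrane protein of the AWPM-19 family, at 3.73 ± 0.09 (13.3-fold). LTP-2, a lipid transfer protein, rose by 2.73 ± 0.07 (6.63-fold), and R1C-Prx, a 1-Cys peroxiredoxin of the kind found in seeds, by 2.16 ± 0.13 (4.47-fold). PP2C30, a phosphatase that restrains ABA signalling, rose by 2.05 ± 0.14, and PBZ1, a pathogenesis-related protein, by 2.15 ± 0.05. PDHE1-A rose by 2.29 ± 0.04, the zinc finger gene OsC3H10 by 1.80 ± 0.23 and Agglutinin, named as a lectin, by 1.79 ± 0.16. Among the genes that fell were EXPB3, a beta-expansin that loosens cell walls (−2.28 ± 0.27), a gene annotated only as peroxidase (−2.05 ± 0.16), GLU14, an endoglucanase (−1.90 ± 0.03), and OSPIN10a (PIN3A), an auxin efflux carrier (−1.76 ± 0.18). The ammonium transporter AMT2-2 fell (−1.73 ± 0.23; its other probe gave −0.26), as did STLP3 (−1.69 ± 0.33), the amylase and protease inhibitor RASI (−1.39 ± 0.42) and IAMT1, which methylates auxin (−1.34 ± 0.26). The limma adjusted p of these 16 genes ran from 6.71e-11 for PM1 to 1.47e-06 for RASI.

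Genes of desiccation tolerance rose as a group under ABA. In the list of late embryogenesis abundant (LEA) proteins and dehydrins, which protect drying cells and seeds, all 6 measured members rose (6 adjusted over the list alone), with a mean of 0.92 and an adjusted p of 2.45e-06 by camera. With an estimated correlation the adjusted p was 0.0209. RAB16B (1.27), EM (1.25 ± 0.21) and rab25 (1.01 ± 0.09) rose most. In the defence list, 4 of 8 members rose and 1 fell (mean 0.55, adjusted p = 0.00872, but adjusted p = 0.139 with an estimated correlation); the chitinase chia4a, an enzyme that cuts chitin, rose by 0.79 ± 0.05. The list of ABA receptors, phosphatases and kinases did not pass as a whole (adjusted p = 0.404): of its 13 probes 4 rose and 3 fell, or 5 rose and 3 fell adjusted over the list alone. The counts of the defence list, and of the redox list below, were the same adjusted over the list alone.

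Lists matched on gene symbols, written later than those above, gave more groups. Of clade A PP2C phosphatases, which hold ABA signalling back, 5 of 6 rose under ABA, with a mean of 1.06 (adjusted p = 1.31e-04; adjusted p = 0.112 with an estimated correlation). PP2C68 rose by 1.73 ± 0.11, while PP2C53 was at 0.01. A wider list of ABA signalling genes (mean 0.30, 11 of 21 probes up, 3 down, adjusted p = 0.00379; adjusted p = 0.112 with an estimated correlation) held opposed members: the kinase SAPK9 fell (−0.92 ± 0.10) and the receptor gene PYL11 fell (−0.71), while VP1, a seed maturation factor, rose by 0.18 ± 0.24. Lipid transfer proteins rose in 5 of 6 cases (mean 0.82, adjusted p = 0.00254), and in the symbol-matched LEA list 6 of 7 members rose and Dhn1 fell (−0.38; mean 0.74, adjusted p = 0.00104). For these 2 lists the adjusted p was 0.112 with an estimated correlation. Genes of diterpenoid phytoalexin synthesis, which make antimicrobial compounds, rose in 5 of 10 cases (mean 0.27, adjusted p = 0.0105; adjusted p = 0.123 with an estimated correlation), led by the cyclase gene CPS2 (1.36 ± 0.16). The symbol-matched defence list shifted up (mean 0.33, 6 of 15 up, 1 down, adjusted p = 0.0105), as did aquaporins, which are water channels (mean 0.08, 12 of 28 up, 2 down, adjusted p = 0.0331); the adjusted p of both was 0.123 with an estimated correlation. Auxin genes shifted down (mean −0.16, 22 of 60 down, 8 up, adjusted p = 0.0430; adjusted p = 0.123 with an estimated correlation), with IAA12, a repressor of auxin responses, at −0.98 ± 0.32. The aquaporin and auxin calls ended without the dye term (adjusted p = 0.0722 and 0.0582), and the auxin call also with scale normalization (adjusted p = 0.0596) and without GA array 07 or 08.

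Across the array, ABA changed 7430 of 17782 probes (41.8 percent; 3209 up, 4221 down) at an adjusted p under 0.05. Most shifts were small, with a median size of 0.21 on the log2 scale among called probes, and 242 were called and at least 2-fold (140 up, 102 down). Without the dye term the count fell to 4443. The p-values measure only the spread between arrays, which may be technical since the labels do not say whether the arrays held separate cultures. Nor do the labels say whether the arrays shared an untreated sample. If they did, a ratio tested against 0 leaves out the spread of the untreated callus. If the untreated samples were separate, their spread is part of the spread between arrays.

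Under GA, the largest named rise was that of AT4 (PMT), an acyltransferase that adds p-coumarate to lignin precursors, at 3.62 ± 0.09 (12.3-fold). EXP8, an alpha-expansin that loosens cell walls, rose by 2.62 ± 0.17 (6.16-fold), and the peroxidase that fell under ABA rose by 2.22 ± 0.17. OsCASPL1U3 and OsCASP1, of the family that organises the Casparian strip, rose by 2.18 ± 0.06 and 1.81 ± 0.21. GDCSH, of the glycine decarboxylase complex, rose by 2.05 ± 0.05, 4CL-3, of phenylpropanoid synthesis, by 1.86 ± 0.08 and the lipoxygenase LOX1.1 by 1.69 ± 0.15. The genes that fell included EM (−2.83 ± 0.14), PM1 (−2.83 ± 0.11), the beta-glucosidase BGLU26 (−2.79 ± 0.14), LTP-2 (−2.41 ± 0.13), rab25 (−2.13 ± 0.26) and R1C-Prx (−1.61 ± 0.16). GL2 (GRF4), a growth-regulating factor, fell (−1.70 ± 0.12), as did GLO1, a glycolate oxidase (−1.60 ± 0.10; its other probe gave 0.00). The limma adjusted p of these 16 genes ran from 4.67e-10 for PM1 to 5.10e-07 for LOX1.1.

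The LEA and dehydrin list that rose under ABA fell under GA. Of its 6 members 4 fell and 2 did not pass (4 fell adjusted over the list alone), with a mean of −1.15 and an adjusted p of 0.00287, but adjusted p = 0.117 with an estimated correlation. The redox list, of enzymes that remove or use peroxide, rose in 5 of 6 probes and fell in 1 (mean 0.91, adjusted p = 0.00287, but adjusted p = 0.121 with an estimated correlation); the catalase CAT-A rose by 1.22 ± 0.27 and the peroxidase named above belongs to the list. Under ABA the redox list did not pass (4 up, 2 down, adjusted p = 0.305). The defence list did not pass (3 up, 1 down of 8, adjusted p = 0.243), although Chib3H-a, a chitinase-like inhibitor, rose by 1.48 ± 0.04. Symbol-matched lists of GA metabolism (1 of 8 probes up, 2 down, adjusted p = 0.512) and GA signalling (3 of 5 down, adjusted p = 0.138) did not pass. GA20OX3, which makes GA, fell (−1.03 ± 0.12), as did the GA receptor gene gid1 (−0.69 ± 0.19) and CIGR2, a GA-responsive transcription regulator (−0.99 ± 0.09), while CYP88A5 (KAO), also of GA synthesis, rose by 0.38 ± 0.18. GF14E, a gene with a 14-3-3 name and the synonym GID2, rose by 0.78 ± 0.11 on 1 probe and was at −0.01 on the other. Of 4 alpha-amylase genes, too few to test, 2 fell under GA (AMY1.2, −1.20 ± 0.40, and AMY1.4, −0.22 ± 0.58) and 2 rose (AMY1.5, 0.17 ± 0.19, and AMY1.3, 0.15 ± 0.91); without the dye term only AMY1.2 passed (adjusted p = 0.00130, against 0.494 for AMY1.4, 0.199 for AMY1.5 and 0.809 for AMY1.3). AMY1.2 rose under ABA (1.19 ± 0.56).

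Among the symbol-matched lists, 3 rose and 3 fell under GA. Aquaporins (mean 0.23, 15 of 28 up, 4 down, adjusted p = 0.0368), jasmonate genes (mean 0.23, 12 of 26 up, 4 down, adjusted p = 0.0422) and sugar genes (mean 0.30, 13 of 24 up, 3 down, adjusted p = 0.0393) rose, with the invertases CIN4 (1.41) and CIN2 (1.13) among the last. Their adjusted p was 0.176, 0.176 and 0.277 with an estimated correlation, and the jasmonate call ended with gene means (adjusted p = 0.123). Heat shock proteins, which refold other proteins, fell (mean −0.21, 10 of 18 down, 3 up, adjusted p = 0.0368), as did chlorophyll synthesis (mean −0.14, 6 of 13 down, adjusted p = 0.0422) and the LEA list (mean −1.02, 5 of 7 down, adjusted p = 0.0136). The adjusted p of these 3 was 0.176 with an estimated correlation, and the chlorophyll call ended with gene means (adjusted p = 0.0817). CLPB1, a disaggregating chaperone, fell (−1.54 ± 0.27), as did the small heat shock protein HSP18.6 (−1.11 ± 0.12). Without GA array 07 none of the 6 lists passed. Expansins and xyloglucan-modifying enzymes did not pass (13 of 31 up, 4 down, adjusted p = 0.0524), but did without the dye term (adjusted p = 0.0356) and without ABA array 23 or GA array 05; XRT5 (XTH8) rose by 0.88 ± 0.05.

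Of the meristem list, 1 of 5 members rose and 2 fell under ABA (adjusted p = 0.697), and 3 rose under GA (adjusted p = 0.173), counts that were the same adjusted over the list alone. HOS9 (OSH71), a homeobox gene of the shoot meristem class, was among them (ABA −0.19 ± 0.05, GA 0.74 ± 0.07). The 2 members of the seed storage list, the glutelin genes GLUA-3 (0.03 under ABA, −0.08 under GA) and GLUB-5 (0.02 and −0.01), did not pass under either hormone; a symbol-matched list of 4 added RA14, which did not pass, and R1C-Prx, given above. A list of 16 photosynthesis probes gave 6 up and 1 down under ABA (adjusted p = 0.0813) and 6 down under GA (adjusted p = 0.395), with PSBW, of photosystem II, at 0.48 ± 0.25 and −0.82 ± 0.11. WRKY transcription factors did not pass as a list (ABA 2 of 6 up, adjusted p = 0.305; GA 1 up and 1 down, or 0 up and 1 down adjusted over the list alone, adjusted p = 0.964). Of the 13 ABA signalling probes 3 rose and 3 fell under GA, the same adjusted over the list alone (adjusted p = 0.964). In a list of 3 cell cycle genes, too small to test, MCM3 (−0.25 ± 0.22) and MCM5 (−0.15 ± 0.07) fell and MCM7 rose (0.16 ± 0.20) under ABA, all of the replicative helicase, and none passed under GA. Without the dye term MCM3 and MCM7 did not pass (adjusted p = 0.0825 and 0.218). ABA8OX1, which breaks ABA down, fell under ABA (−0.44 ± 0.40) and rose under GA (0.86 ± 0.29); without the dye term the fall under ABA did not pass (adjusted p = 0.058).

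GA changed 8715 of 17782 probes (4660 up, 4055 down; 4283 up and 4289 down with quantile normalization), with a median size of 0.25 among called probes. Of these, 362 were called and at least 2-fold (229 up, 133 down). Without the dye term GA called 6246 probes.

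With directions as labelled, the largest named differences between ABA and GA were in genes given above under each hormone. The difference ABA minus GA was 6.56 for PM1, 5.14 for LTP-2, 4.07 for EM, 3.77 for R1C-Prx and 3.31 for BGLU26. It was −4.26 for the peroxidase, −3.98 for AT4, −3.35 for EXP8, −3.08 for AMT2-2 and −3.06 for OsCASPL1U3, and the limma adjusted p of these 10 genes ran from 9.59e-12 for PM1 to 8.45e-08 for EXP8. Were the GA arrays turned, PM1 would differ by 0.91, LTP-2 by 0.32, EM by −1.58 and AT4 by 3.26, and the peroxidase would not pass (0.17, adjusted p = 0.110). As a list, LEA proteins and dehydrins were higher under ABA than under GA by 2.07 (adjusted p = 8.64e-06; adjusted p = 0.0259 with an estimated correlation) and redox genes lower (−0.98, adjusted p = 0.0264; adjusted p = 0.245 with an estimated correlation). The redox call ended with scale normalization (adjusted p = 0.0611) and gene means (adjusted p = 0.0764). With GA turned the LEA difference would not pass (−0.22, adjusted p = 0.937), redox genes would be higher under ABA (0.83, adjusted p = 0.0101) and the defence list would pass (0.80, adjusted p = 0.00558). Among symbol-matched lists, clade A PP2C phosphatases (1.01), heat shock proteins (0.36), ABA signalling (0.32) and chlorophyll synthesis (0.23) were higher under ABA, and jasmonate genes (−0.31) and redox genes (−0.40) lower, with adjusted p from 0.0178 to 0.0461. With an estimated correlation the adjusted p was 0.179 for each of these lists. Gene means ended the calls of ABA signalling, chlorophyll synthesis, jasmonate and redox genes (adjusted p from 0.0579 to 0.124), and with GA turned only the PP2C phosphatases would keep theirs (1.10, adjusted p = 4.70e-04). Other symbol-matched lists would gain a call, so that 8 would pass by camera (adjusted p up to 0.0319). Sugar (0.40), aquaporin (0.31), defence (0.53) and lipid transfer genes (0.66) would be higher under ABA. Ribosomal (−0.24), DNA replication (−0.19) and proteasome genes (−0.20) would be lower.

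With directions as labelled, probes changed in opposite directions outnumbered those changed the same way. ABA raised and GA lowered 1041 probes, and ABA lowered and GA raised 1720, against 732 and 1106 if the calls were independent. Both hormones raised 645 and both lowered 1215, against 841 and 963. Among probes called and at least 2-fold under both, 58 and 32 were opposed and 1 and 2 moved the same way; CLPB1 (ABA 1.22 ± 0.17) and HSP18.6 (ABA 1.19 ± 0.10) were among the opposed. Over all probes the mean ratios correlated at r = −0.34 (Spearman rho −0.15). Simulations with no change gave r = 0.80 with a shared untreated sample and −0.00318 with separate ones. The 0.80 was fixed by the spread assumed for the shared sample and is no estimate from these arrays. The direction of the GA arrays is open: turned, they would make the opposed changes shared ones and r 0.34. The contrast called 8889 probes (50.0 percent, 4042 higher and 4847 lower under ABA). The majority reversed with quantile normalization (4741 higher, 4432 lower) and would reverse with the GA arrays turned (4120 higher, 3887 lower). The array numbers of the hormones fall in separate ranges, so any batch of arrays cannot be told apart from the hormone.

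Arrays of one hormone and dye orientation correlated at 0.936 to 0.939 for ABA and 0.870 to 0.957 for GA, once each was turned to treated over untreated. Between orientations the values were 0.506 to 0.605 for ABA and 0.701 to 0.817 for GA, with rank correlations of only 0.156 to 0.298 and 0.470 to 0.635. An ABA and a GA array correlated at −0.40 to −0.32 with opposite dyes and at −0.28 to −0.02 with the same dye; the rank correlations were −0.35 to −0.16 and −0.09 to 0.24. The dye term itself was called for 7576 probes (42.6 percent), 38 of them at least 2-fold, and its SD over probes was 0.23, against 0.28 for ABA and 0.33 for GA.

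**Figure D1:**
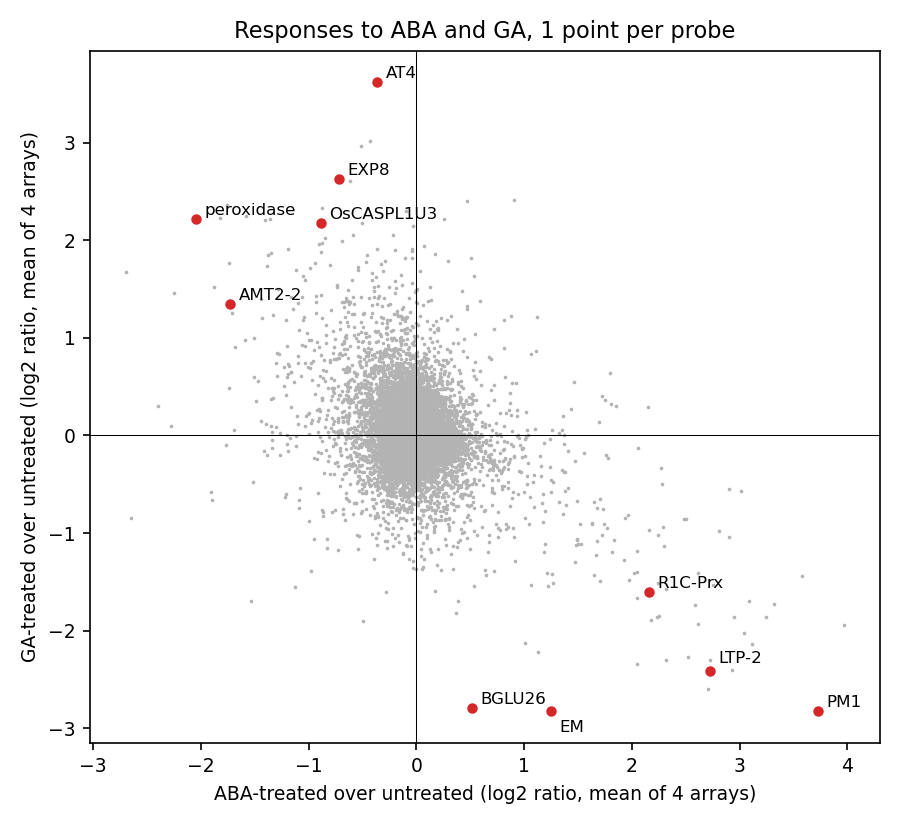
Mean log2 treated over untreated under ABA (horizontal) and GA (vertical) for the 17782 tested probes, r = −0.34. PM1, LTP-2 and EM lie towards high ABA and low GA, AT4 and EXP8 towards high GA.

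**Figure D2:**
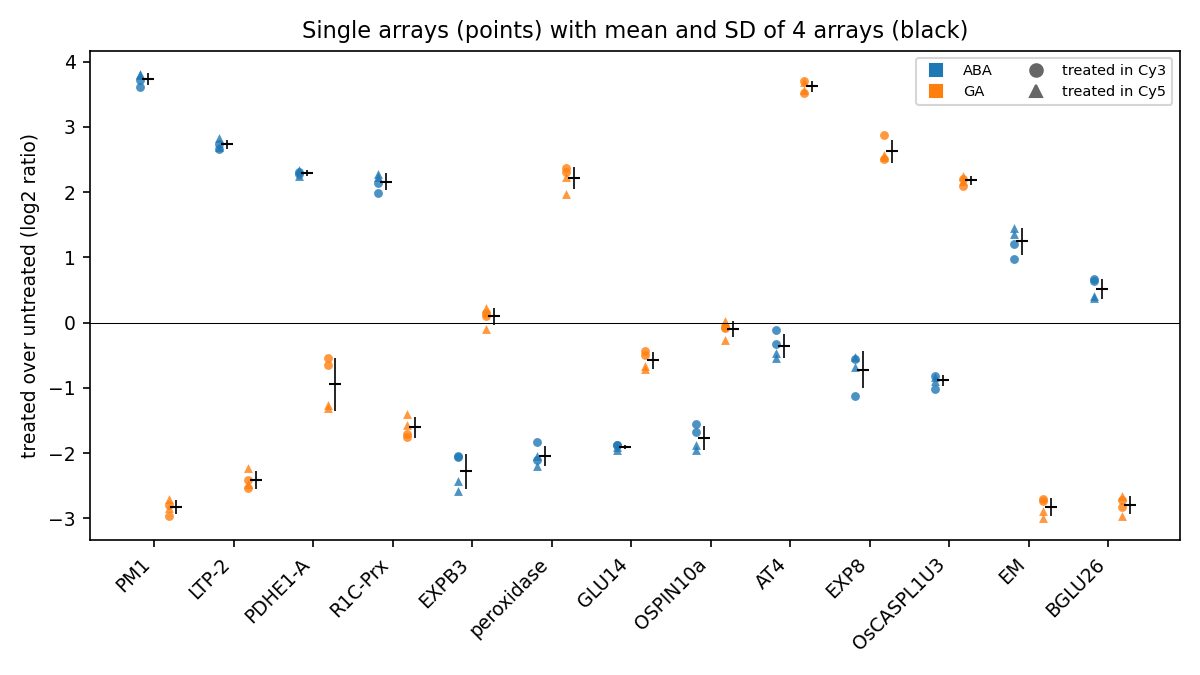
Log2 treated over untreated of named genes on each of the 8 arrays, with ABA and GA arrays marked apart and the dye of the treated sample shown. PM1 averaged 3.73 under ABA and −2.83 under GA.

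**Figure D3:**
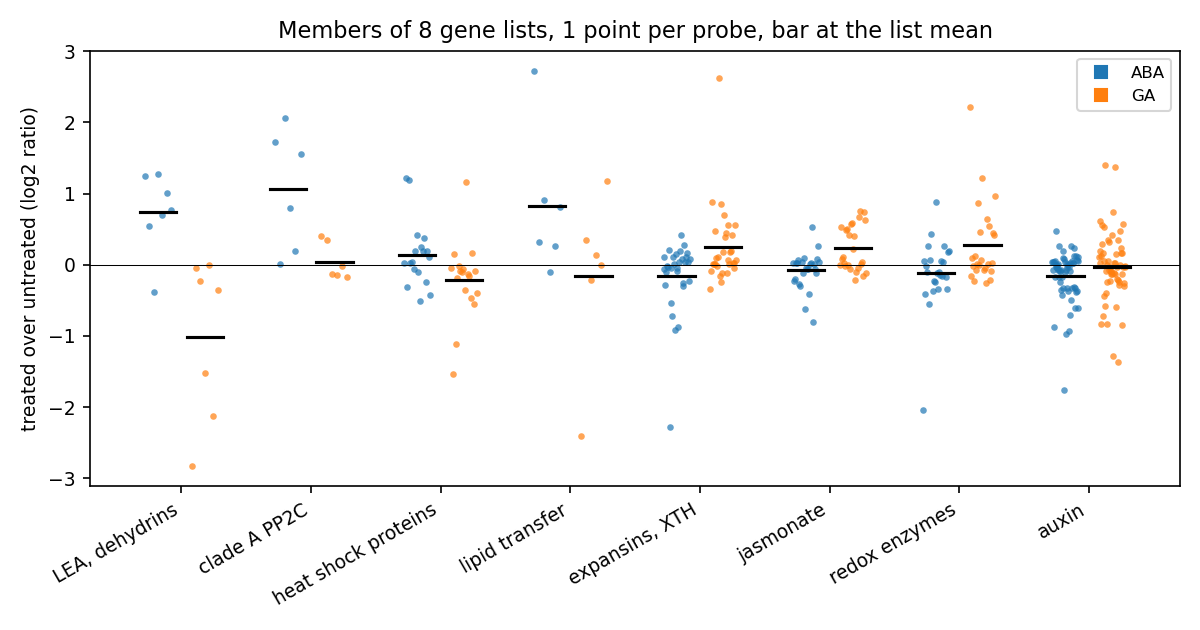
Log2 treated over untreated of each member of 8 symbol-matched lists under ABA and under GA. The lists shown were picked after the results were seen; the LEA mean was 0.74 under ABA and −1.02 under GA.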

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

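Which tests are weighed here was decided partly after results were seen: the tests on dye labels, dye bias and turned GA arrays were chosen after the opposed responses had been seen, and the tests on other arrangements of the arrays before. The symbol-matched lists whose members are given below were also picked after their results were seen.

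With directions as labelled, ABA and GA differed by limma in 90 of 96 named probes and in 8889 probes in all (50.0 percent). The named probes were picked from these same data for large changes or small p, so their high share follows from the choice. With the GA arrays turned the counts would be 75 and 8007, and PM1 would differ by 0.91, so the values below hold for the labelled direction only. Genes higher under ABA than under GA on the log2 scale were PM1 by 6.56, LTP-2 by 5.14, EM by 4.07, R1C-Prx by 3.77, BGLU26 by 3.31, PDHE1-A by 3.23, rab25 by 3.14, CLPB1 by 2.76, AMY1.2 by 2.39, HSP18.6 by 2.30, PP2C30 by 2.19, GL2 by 2.08, PBZ1 by 1.86, OsC3H10 by 1.48, GH3-8 by 1.42, PP2C68 by 1.32, GLO1 by 1.32, chia4a by 1.31, RFS by 1.31, PSBW by 1.30, CPS2 by 1.16, Agglutinin by 1.15, SUS4 by 1.12, CAO by 1.09, VP1 by 1.04 and CIGR2 by 1.03. Smaller differences the same way were GA20OX3 0.95, WOX11 0.72, CYP76M8 0.72, RAB16C 0.71, RK2 0.69, gid1 0.65, RAB16D 0.59, WOX6 0.56, REK 0.55, IAA9 0.47, PORB 0.47, RCABP69 0.44, AMY1.4 0.44, ISP 0.42, CIGR1 0.39, aquaporin PIP1-1 0.35 by 1 probe, WRKY62 0.33, chaperonin 0.25, aquaporin PIP2-1 0.25, wrky38 0.23, EXP1 0.20, CYP714D1 0.17, MCM7 0.15 and TIP2-2 0.13. The other probes of GLO1 (0.08), REK (0.07) and CYP76M8 (0.02) did not pass.

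Genes lower under ABA than under GA had ABA minus GA values of −4.26 for the peroxidase, −3.98 for AT4, −3.35 for EXP8, −3.08 for AMT2-2 (−1.19 by its other probe), −3.06 for OsCASPL1U3, −2.60 for STLP3, −2.37 for EXPB3, −2.26 for GDCSH, −2.23 for LOX1.1, −1.88 for SAPK9, −1.86 for OsCASP1, −1.72 for IAA12, −1.68 for 4CL-3, −1.67 for OSPIN10a, −1.56 for JAZ7, −1.33 for GLU14, −1.30 for IAMT1, −1.30 for ABA8OX1, −1.21 for RSS1, −1.19 for RASI, −1.18 for OPR10, −1.16 for XRT5 and −1.06 for Chib3H-a. Smaller ones were −0.93 for HOS9, −0.93 and −0.22 for the 2 probes of GF14E, −0.83 for TPP1, −0.76 for JAZ4, −0.60 for CYP88A5, −0.58 for Cht10, −0.57 for OSH1, −0.57 for PIP1-2, −0.52 for PIP2-4, −0.45 for the other PIP1-1 probe, −0.37 for JAZ10, −0.37 for LTP110-A, −0.35 for CAT-A, −0.33 for PP2C53, −0.27 for MCM3 and −0.22 for SPY. The list means that differed were those of LEA proteins (2.07 in the list fixed first, 1.75 in the symbol-matched one), redox genes (−0.98 and −0.40), clade A PP2C phosphatases (1.01), heat shock proteins (0.36), ABA signalling (0.32), chlorophyll synthesis (0.23) and jasmonate genes (−0.31). Only the LEA list fixed first kept its call with an estimated correlation (adjusted p = 0.0259); the adjusted p was 0.245 for the redox list fixed first and 0.179 for each symbol-matched list.

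In 8 of 202 groups of 4 arrays, 1 array lay far from the others, and about 1 in 20 would by chance. The ratios of gap to range were 0.966 for JAZ10 under ABA, 0.921 for EXP1 under ABA, 0.913 for RFS under GA, 0.882 for RA14 under GA, 0.871 for LOX1.1 under ABA, 0.849 for EXP8 under GA and 0.849 for GF14E under ABA. The spread of ratios over all probes (median absolute deviation) gave 0.847 for the GA arrays, with array 08 at 0.270 and the others at 0.196 to 0.208.

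The responses to ABA and GA were opposed across probes, which could come from opposed action of the hormones, or from dye labels swapped on the arrays of either. For ABA, the LEA list mean of 0.92 (SE 0.12 over 6 genes, some of them looked at when the direction was set) argues against swapped labels, since these genes are known to rise with ABA. For GA, the mean of GA20OX3 and gid1 was −0.86 (SE 0.17 over 2 genes), a fall known as feedback on GA, but 2 genes are too few. GA20OX3, like AMY1.2 below, was also looked at when the direction was set. Of 4 alpha-amylase genes only AMY1.2, which fell (−1.20), passed without the dye term (limma adjusted p = 0.00130). This family is known to rise with GA in seeds, which need not hold for these genes in callus. A swap on the GA arrays therefore cannot be decided. Dye bias shared by arrays of 1 orientation cancels in a mean of 1 Cy3 and 1 Cy5 array. All 16 pairs of such ABA and GA means were opposed (highest rank correlation −0.10, highest r −0.31). Such bias already cancels in the hormone means over all arrays, since each hormone has as many Cy3 as Cy5 arrays. The pairs reuse these arrays, so they repeat the main result and are no separate evidence on dye bias.

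The number of probes called between ABA and GA, 8889, was the highest of 35 arrangements of the arrays (1 of 35). The next, at 1406, was the split by dye orientation, and after it the highest was 21. The dye term, at 7576 probes, was likewise highest in 1 of 35. The next, at 5953, was the split by hormone, and after it the highest was 1. The other splits leave much or all of the hormone difference, or of the dye effect, in the residual spread, which lowers their counts. The ranks therefore favour the real split, and the split by hormone cannot be told apart from any batch of arrays. For ABA and for GA against untreated, the true signs gave the most calls in 1 of 8 arrangements each, against 14 and 38 probes for the next; 8 arrangements are too few for a share under 0.05.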

How the results depend on the processing

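The tests given in this part repeat those of the report; keeping unlisted features, keeping exact zeros, turning the GA arrays, and symbol lists with no names taken out were chosen after the data were seen. No paired analysis was possible because the labels give no culture or replicate shared between the ABA and GA arrays. With the GA arrays turned, r between the hormones would be 0.34, ABA minus GA would be called for 8007 probes, and differences such as those of AT4 (3.26), EM (−1.58), BGLU26 (−2.27) and the redox list fixed first (0.83) would reverse. No named gene or list that passed in either setting reversed under any other alternative it was run with. Lists were not run with quantile normalization, robust moderation, array weights, a dye term for each hormone or each hormone on its own arrays. Nor were they run with unlisted features or exact zeros kept. With quantile normalization the majority of calls turned for ABA minus GA (4741 higher, 4432 lower) and for GA (4283 up, 4289 down). Turning the GA arrays would also reverse the majority for ABA minus GA (4120 higher, 3887 lower). Of 202 pairs of a named gene and a comparison, 178 kept their side of the threshold under every alternative run on them, with no reversal of a call. A change of sign where neither setting passed was not counted. Turning the GA arrays, the 2-fold minimum and the stricter adjusted p are not among these alternatives. Fitting each hormone on its own arrays was not run for pairs of ABA minus GA. In single tests of named genes 3976 stayed the same, 40 lost the call and 14 gained it. Leaving out 1 array at a time gave 5541 to 8864 probes for ABA, 7241 to 9663 for GA and 7558 to 9916 for ABA minus GA.

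Without the dye term ABA called 4443 probes, against 7430. A 2-fold minimum left 242 for ABA, 362 for GA and 820 for ABA minus GA, by its construction. With a dye term for each hormone, the dye effect was called for 5006 probes on the GA arrays and 8251 on the ABA arrays, against 7576; the cause was not tested. Spearman correlation gave −0.15 between the hormones, and, between arrays of opposite dye orientation, a mean of 0.22 for ABA and 0.56 for GA, against r of −0.34, 0.55 and 0.76; the cause was not tested.

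Of the lists fixed first, 2 passed in each comparison. With an estimated correlation 1 passed for ABA, 0 for GA and 1 for ABA minus GA, and scale normalization and gene means each left 1 for ABA minus GA. The redox list is the one lost there (adjusted p 0.061 and 0.076). Of the symbol-matched lists, 8, 6 and 7 passed for ABA, GA and ABA minus GA, and 0, 0 and 0 with an estimated correlation. Gene means left 3 for ABA minus GA. Leaving out 1 array gave 0 to 8 for GA and 2 to 10 for ABA minus GA: without GA array 07 none passed under GA and 2 between the hormones, and without GA array 08 3 did. The auxin list under ABA lost its call without GA array 07 or 08 (adjusted p 0.054 and 0.058), without the dye term (0.058) and with scale normalization (0.060), and the aquaporin list without ABA array 19 (0.058) or the dye term (0.072). Under GA, gene means ended the jasmonate (0.123) and chlorophyll (0.082) calls, and the latter also ended without ABA array 20 (0.053). OSH1 under GA lost its call without GA array 08 (0.054). Lists that gained a call were photosynthesis under ABA without ABA array 23 (0.042), expansins under GA without the dye term (0.036), ABA array 23 (0.039) or GA array 05 (0.047), and ribosome under GA with scale normalization (0.046) and without ABA array 23 (0.0495), GA array 04 (0.037) or GA array 05 (0.045). For ABA minus GA, diterpenoid phytoalexins gained a call with scale normalization (0.0494), and these, expansins and photosynthesis without ABA array 23 (0.0466). With no names taken out, the ribosome list also passed under ABA (adjusted p 0.0341) and GA (0.0258). The cause of these changes was not tested. Signal over background was not held, so its limit on weak probes is not analysed here.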

Other observations

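The patterns below were looked at after the results were seen, and no tests were chosen for them beyond those of the report. Lists of DNA replication, ribosomal proteins and cyclins passed under neither hormone, although the ribosome list under GA passed with scale normalization (adjusted p = 0.0458) and without ABA array 23, GA array 04 or GA array 05. Of 28 DNA replication probes, 12 fell under ABA (adjusted p = 0.156) and 12 under GA (adjusted p = 0.0568); PCNA, the replication clamp (annotated Cyclin), fell under both (−0.36 ± 0.12 and −0.54 ± 0.12, n = 4 arrays). RPA1C, which binds single-stranded DNA, did the same (−0.42 ± 0.06 and −0.46 ± 0.09). Of 20 ribosomal protein probes 9 fell under each (adjusted p = 0.0608 and 0.0507). Of 20 cyclin and kinase probes, 4 rose and 8 fell under ABA (adjusted p = 0.225), and 7 rose and 4 fell under GA (adjusted p = 0.673). Among D-type cyclins, which start the division cycle, CYCD5-2 fell under ABA (−0.77 ± 0.20) and rose under GA (0.45 ± 0.25), while CYCD3-2 fell under both (−0.23 ± 0.04 and −0.78 ± 0.29).

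Transporters and metal-binding proteins held strongly changed single genes in lists that did not pass. The zinc transporter gene ZIP4 rose under ABA (1.24 ± 0.18) and fell under GA (−0.33 ± 0.17). SPX3, of phosphate signalling, fell under ABA (−1.21 ± 0.05) and rose under GA (0.41 ± 0.03). The sugar transporter genes SWEET1B (0.72 ± 0.24 and −1.39 ± 0.22) and SWEET15 (0.60 ± 0.27 and −0.72 ± 0.27) rose under ABA and fell under GA, and the metallothionein gene MT21A did too (0.68 ± 0.02 and −1.09 ± 0.11), although 6 of 9 metallothionein probes rose under GA and 2 fell (mean 0.23), MT4A by 1.13 ± 0.08 among those that rose. RR9, a response regulator of cytokinin, rose under GA (1.63 ± 0.08) and fell under ABA (−0.37 ± 0.11). The adjusted p of the lists of phosphate, iron and zinc, metallothionein, sugar transport and cytokinin genes ran from 0.156 to 0.957 under ABA and from 0.189 to 0.776 under GA.

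The first 216 features of the table, which carry no gene, had median dye ratios (log2) of −2.45, −2.79, −3.17 and −3.36 on ABA arrays 24, 20, 19 and 23, and of −0.53, −0.54, −0.36 and −0.85 on GA arrays 04, 05, 07 and 08. Over these features the dye ratios correlated at 0.96 to 0.99 between ABA arrays and at 0.13 to 0.63 between GA arrays. Between an ABA and a GA array they correlated at −0.84 to −0.23. The cause was not tested.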
